A study of Mus musculus with 8 samples.

How the data were processed

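ATAC-seq libraries came from 8 samples of RHKI mouse embryonic stem cells, 4 controls and 4 treated with doxycycline (500 ng/ml, 48 h), grouped by the sample titles. Nothing in the labels says whether the replicates were separate cultures. Per the submitters' processing notes, Trimmomatic 0.39, Bowtie2 2.5.0, Picard 2.10.9, SAMtools 1.16.1, HOMER 4.11 and deepTools 3.5.1 were used and the genome build was GRCm38. The role and order of these tools, the peak caller and its threshold, the handling of reads that match several places, and whether the 8 samples were pooled are not given in the sources used here.

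The deposited peak list holds positions only: 76996 lines of 3 columns with a chromosome, a start counted from 0 and an end. No column holds a score, a height or a value of a sample (0 columns of values per sample were left out). Peaks did not overlap, and the smallest gap between neighbours was 201 bp, with 0 gaps of 200 bp or less. The planned comparisons of Dox with control per region and of control with Dox peak sets were therefore not run, and neither depth nor precision per sample can be given. Binomial intervals cover only the counting of genes.

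Genes came from the RefSeq table of GRCm38.p6, which lists outer bounds and no strand, exons or sequence. Of 21900 protein-coding genes, 126 with scaffold, patch or mitochondrial positions were left out (13 of them mitochondrial), which left 21774. The build was checked by shifting the peaks: 22.5% overlapped a window at a gene end in place, against 6.63% and 6.55% after shifts of 10 kb in either direction and 5.90% and 6.05% after shifts of 100 kb. Because strand is missing, the planned windows at transcript starts became windows of 1 kb on either side of both gene ends, with an overlap of 1 bp. The planned classes of exon, intron and UTR became gene end, inside a protein-coding gene, inside another gene and outside genes, by peak centre. The planned motif, GC content and GC skew results need sequence and were not run.

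Chance was taken from 1000 placements of the same peak widths at random positions within the span of their chromosome, with two-sided permutation p-values and Benjamini-Hochberg adjustment over classes. The 16 gene lists were fixed before the data were examined, and all 230 named genes matched (Hox and olfactory receptor genes were taken by symbol). Shares of list genes with a peak at an end were set against all other protein-coding genes by two-sided Fisher's exact tests, adjusted over the lists. Distal peaks have their centre over 1 kb from every protein-coding gene end (60120 peaks, 78.1%) and were counted within 50 kb of either end of a gene. List means were compared with 10000 random lists matched on deciles of the number of protein-coding genes within 50 kb. The genes named from each list are the first 2 with and the first 2 without a peak at an end in the written order (4 of each for naive pluripotency and R-loop factors), with Rnaseh1, H2az1, H2az2 and the genes nearest to the 5 widest peaks. A gene that this rule names is not reported here. Others, such as Tet1, Prdm14, Cbx7, Dnmt3a, Ttr, Aqr, Dhx9, Srcap, Ep400, Gdf3 and the genes on X, were chosen after their values were seen.

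The procedures were tested on simulated data. With 98% of R-loop or polycomb genes given a peak and 60% of other genes, the end test called the lists in 20 and 16 of 20 sets, and it called 2 of 240 lists left at the base share. With 8 extra distal peaks per naive pluripotency gene, the distal test called that list in 20 of 20 sets. It called 3 of 260 lists with no peaks added, but the Hox clusters in 3 of 20 sets and the olfactory receptors in 20 of 20 sets. Apart from the 8 extra peaks, distal peaks were placed independently of each other in these sets, while the real ones gather in clusters. The rates of false calls may therefore be too low for the real list. Random peaks gave a fold at gene ends of 0.982 to 1.03 in 5 sets.

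Alternatives tried were windows of 500 bp and 5 kb, all annotated genes, the peak centre, peaks wider than the median, other placements and matchings, distal reaches of 20 kb and 100 kb, and autosomes alone, with 300 placements each where peaks were placed. Calculations used Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1 and pandas 2.3.3, with matplotlib 3.10.9 for figures.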

Results

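Accessible chromatin was measured by ATAC-seq, in which Tn5 transposase inserts sequencing adapters into open DNA, in 8 samples of the mouse embryonic stem cell line RHKI. RHKI is a derivative of the E14Tg2a line with an HA-tagged Rnaseh1 knock-in, and RNase H1 degrades the RNA strand of the RNA-DNA hybrids in R-loops. The 4 control samples were left without doxycycline and the 4 Dox samples received 500 ng/ml doxycycline for 48 h, all in 2i/LIF medium, which holds embryonic stem cells in the naive pluripotent state. By its title the series concerns R-loops, the placement of the histone variant H2A.Z and lineage choice, and the ATAC-seq arm sets Rnaseh1-inducible cells given doxycycline against untreated ones. Induction itself was not measured here. The peaks used here formed 1 list for the whole series, with a chromosome, a start and an end for each peak and no height, count or group. Accessibility in Dox samples was therefore not compared with controls, no value below has a replicate error, and the read depth behind the peaks is unknown. The results describe where the open regions of these naive cells lay, with random placements of the same peaks or exact binomial intervals as the error.

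Of the 5 widest open regions, 3 lay at gene ends. The widest, of 1233 bp (chromosome 11, 58330047 to 58331279, GRCm38), lay at neighbouring ends of Sh3bp5l and Zfp672. A peak of 1221 bp lay at an end of Dennd5b (chromosome 6, 149100502 to 149101722) and a peak of 1037 bp at an end of Rest (chromosome 5, 77265217 to 77266253). Rest encodes a repressor of neuronal genes. A peak of 1060 bp lay inside Fancc, a Fanconi anaemia repair gene (chromosome 13, 63430808 to 63431867), and a peak of 1090 bp lay 10330 bp outside Wapl, which encodes the cohesin release factor (chromosome 14, 34660959 to 34662048). The whole list held 76996 peaks, of which 76968 lay on chromosomes 1 to 19, X and Y. Peak widths ran from 90 to 1233 bp with a median of 130 bp and quartiles of 115 and 156 bp. Peaks covered 0.435% of the 2661 Mb spanned by these chromosomes, at 28.9 peaks per Mb.

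Open regions were concentrated at the ends of protein-coding genes and sparse outside annotated genes. Of the peaks, 22.5% overlapped a window of 1 kb on either side of a gene end, against 3.43% ± 0.0674 (SD, 1000 random placements), a 6.54-fold excess (two-sided permutation p = 0.002, the smallest these placements can give). The gene table gives outer gene bounds without strand, so a gene end here is either the start or the end of the gene. By peak centre, 16848 peaks (21.9%, 6.81-fold over random placement) lay at gene ends and 32002 (41.6%, 1.06-fold) deeper inside protein-coding genes. A further 5762 (7.49%, 0.914-fold) lay in other annotated genes and 22356 (29.0%, 0.590-fold) outside all of them. All 4 classes differed from random placement with an adjusted permutation p of 0.002. The placements put peaks independently of each other and did not avoid unsequenced stretches, while the real peaks gather in clusters. The spread of random placement may therefore be too small, which matters most for the 1.06-fold and 0.914-fold classes. Peaks at gene ends had a median width of 134 bp against 129 to 130 bp in the other classes, and 14.9% of them were over 200 bp wide against 7.60% elsewhere. With a window of 5 kb the excess was 2.84-fold.

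**Figure D1:**
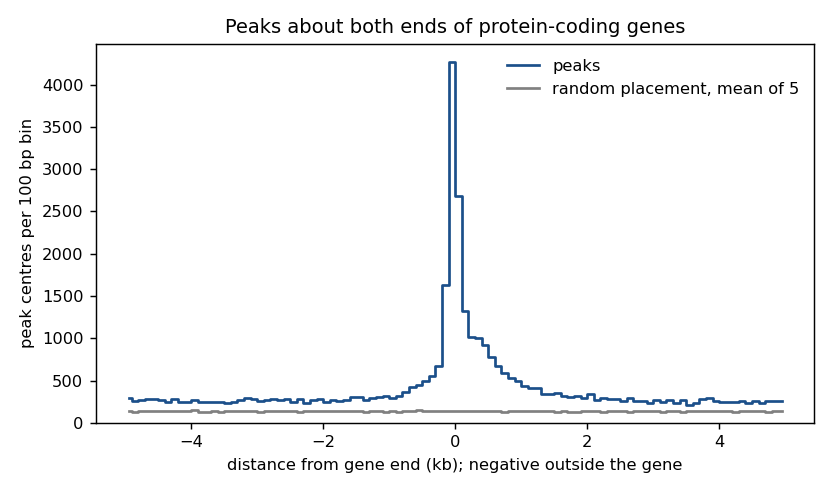
Number of peak centres in bins of 100 bp about both ends of 21774 protein-coding genes (x axis, kb, negative outside the gene), for the peaks and for the mean of 5 random placements. The highest bin, from -100 to 0 bp, holds 4273 centres against 137 in random placements.

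A peak at a gene end was found for 13424 of the 21774 protein-coding genes, or 61.7% (exact 95% binomial interval 61.0 to 62.3%), where random placement gave 12.2% ± 0.238 (SD, 200 placements). Rnaseh1 itself (chromosome 12, 28649601 to 28659592) had a peak at each end, and the peak at the lower end lay at 28649514 to 28649652. Reads from the knock-in were not told apart from those of the endogenous gene here. H2az1 (chromosome 3, 137864487 to 137866922), which encodes the histone variant H2A.Z, also had a peak at each end, and its paralog H2az2 (chromosome 11, 6427226 to 6444511) had 1 peak, at its upper end. Among genes of at least 10 kb, where the ends can be told apart, 8557 (61.5%) had peaks at 1 end, 1280 (9.20%) at both and 4081 (29.3%) at neither. Counting peaks anywhere in the gene raised the share to 73.1%, and counting only peaks wider than the median lowered it to 41.5%. A gene without a listed peak was not shown to be closed, because the threshold and depth behind the list are unknown.

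All 22 genes of the R-loop list had a peak at an end (100%, exact 95% interval 84.6 to 100%), against 61.6% of the other protein-coding genes. The list includes the RNase H2 subunit genes Rnaseh2a, with a peak at each end, Rnaseh2b, with 2 peaks at its lower end, and Rnaseh2c, with 1 peak, together with the helicase genes Aqr and Dhx9. The difference passed Fisher's exact test with Benjamini-Hochberg adjustment over the 16 lists (adjusted p = 0.000229). All 15 polycomb genes also had a peak at an end (exact 95% interval 78.2 to 100%, adjusted p = 0.00279), among them Ezh2, the methyltransferase of histone H3 lysine 27, and its partner Eed. Of the 21 genes that encode H2A.Z or act in its deposition or removal, 19 had a peak at an end (90.5%, exact 95% interval 69.6 to 98.8%, adjusted p = 0.0156), with the SRCAP and EP400 remodeller genes Srcap and Ep400 among them. The 2 without were Kat5 and Ruvbl2, whose nearest peaks lay 1114 and 1041 bp from an end. The H2A.Z call was lost when genes were permuted within deciles of gene length (permutation test, adjusted p = 0.0732), with a 500 bp window (0.158) and with peaks wider than the median (0.254). The polycomb call was lost with peaks wider than the median (Fisher's exact test, adjusted p = 0.254). High shares were not particular to these lists. Of 575 autosomal genes of ubiquitously expressed families, some of them also in the R-loop list, 537 (93.4%) had a peak at an end. The other protein-coding genes also include 1105 olfactory receptor genes, of which 1.90% had one. The lists were not tested against ubiquitously expressed genes alone.

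Of 24 naive pluripotency genes, 20 had a peak at an end (83.3%, exact 95% interval 62.6 to 95.3%), against 61.6% of other genes, which did not pass adjustment (Fisher's exact test, adjusted p = 0.078). Pou5f1 (chromosome 17, 35506032 to 35510777), Nanog (chromosome 6, 122707489 to 122714633), Sox2 (chromosome 3, 34649995 to 34652461) and Klf2 (chromosome 8, 72319062 to 72321654), which encode core pluripotency transcription factors, each had 1 peak at the lower end. The nearest peak to Pou5f1 lay at 35505881 to 35506017, its inner edge 14 bp outside the gene. The 4 genes without a peak at an end were Esrrb, Dppa3, Nr5a2 and Lifr, and their gene bodies overlapped 21, 1, 8 and 10 peaks. Their nearest peaks lay 3714, 1164, 1948 and 8401 bp from an annotated end. The list passed the exact test with a window of 500 bp (adjusted p = 0.0187) and with peaks counted anywhere in the gene (0.00325), and its adjusted p over 10 alternatives ran from 2.92e-05 to 0.161.

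Peaks at gene ends were rare in 3 lists, those of differentiated tissues, olfactory receptors and the two-cell-like state. Of 18 markers of differentiated tissues 3 had a peak at an end (16.7%, exact 95% interval 3.58 to 41.4%, adjusted p = 0.000651). These were Apoa1, Myod1 and Ttr, while the albumin gene Alb and the insulin gene Ins1 had none, the peak nearest to Ins1 lying 134511 bp away. The call was lost over all annotated genes (exact test, adjusted p = 0.126). Of 1105 olfactory receptor genes 21 had a peak at an end (1.90%, 1.18 to 2.89%, odds ratio 0.0105 by Fisher's exact test). These genes are short, with a median of 0.951 kb against 17.2 kb for all protein-coding genes, and within deciles of gene length the difference from other genes shrank from -63.0 to -17.7 percentage points. Of 13 genes of the two-cell-like state 2 had a peak at an end (15.4%, exact 95% interval 1.92 to 45.5%, adjusted p = 0.00279), Duxf3 and the translation initiation factor gene Eif1a. Zscan4c and Zscan4d had none. This call was lost in permutations within deciles of gene length (adjusted p = 0.0732), over all annotated genes (exact test, 0.128) and with peaks wider than the median (0.175). Several two-cell-like genes, the Zscan4, Tcstv and Tdpoz genes among them, belong to families of near-identical copies, so their missing peaks are uncertain.

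The remaining 9 lists, those of lineages, germline, fibroblasts, housekeeping and Hox genes, did not pass the exact test at gene ends (adjusted p from 0.108 to 1). Neuroectoderm genes had a peak at an end in 13 of 15 cases (86.7%), including Sox1 and Nes, while Pax6 and Neurod1 had none. Mesoderm genes had 10 of 15 (66.7%), with Mixl1 and Eomes among them and T (brachyury) and Gsc without. Formative genes, which come on as cells leave the naive state, had 8 of 13 (61.5%), with Dnmt3b and Pou3f1 among them and Fgf5 and Otx2 without. Primitive endoderm genes had 7 of 15 (46.7%), with Foxa2 and Foxa1 among them and the lineage regulators Gata6 and Gata4 without. Trophectoderm genes had 5 of 14 (35.7%), with Tfap2c and Krt8 among them and Cdx2 and Elf5 without. Germline genes had 12 of 15 (80.0%), with Dazl and Ddx4 among them and Tex101 and Taf7l without, and fibroblast genes 6 of 15 (40%), with Col1a1 and Col1a2 among them and Col3a1 and Thy1 without. Housekeeping genes had 11 of 15 (73.3%), with Gapdh and Tbp among them and Actb and Hprt without, and the 39 Hox genes had 21 (53.8%), with Hoxa10 and Hoxa13 among them and Hoxa11 without. Some genes named as without fell just past the 1 kb limit. Their nearest peak lay 1019 bp from an end at Otx2, 1020 bp at Cdx2, 1120 bp at Pax6 and 1147 bp at Actb. At others it lay farther off, 11019 bp at Elf5, 11558 bp at Gsc, 12274 bp at Gata6 and 26104 bp at Hprt. E14Tg2a cells, from which RHKI derives, are known to lack functional Hprt. Whether the missing peak at Hprt reflects accessibility was not determined. Trophectoderm genes passed as lower with a 500 bp window (exact test, adjusted p = 0.0286), but lay higher than other genes without passing with a 5 kb window (85.7%, 0.620) and with peaks anywhere in the gene (85.7%, 0.436). With a 5 kb window Hox (0.00133), formative (0.0391) and neuroectoderm genes (0.0261) passed as higher and fibroblast genes (0.0158) as lower. The exact test takes genes as independent, but neighbouring Hox genes can share a peak in such windows. The peak at 96303166 to 96303301 on chromosome 11 lay within 5 kb of Hoxb3, Hoxb5 and Hoxb6.

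**Figure D2:**
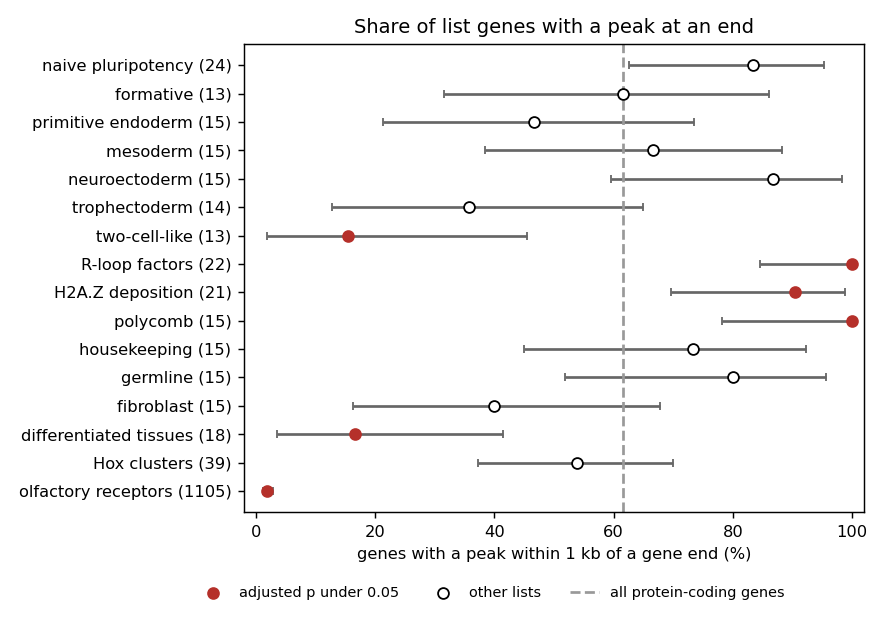
Share of the genes of each list with a peak within 1 kb of a gene end (x axis, %), with exact 95% binomial intervals, the number of genes in brackets, and filled points for lists past an adjusted p of 0.05. R-loop, polycomb and H2A.Z lists lie above the 61.7% of all protein-coding genes (dashed), and the two-cell-like, differentiated tissue and olfactory receptor lists below.

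Naive pluripotency genes stood out most by the open regions around them. They had 11.9 ± 3.81 distal peaks per gene (SD, 24 genes) within 50 kb, where distal peaks have their centre over 1 kb from every protein-coding gene end. Random lists matched on local gene density had 4.51, so the list lay 2.63-fold higher (two-sided permutation test, adjusted p = 0.00107). Tet1 had 19, Nanog 18 and Prdm14 17 distal peaks, and the genes without a peak at an end were also surrounded, with 14 at Esrrb, 12 at Dppa3, 14 at Nr5a2 and 13 at Lifr. Some single genes outside the lists had more, with 37 at Mtcl1 and 29 at Slc2a3, a neighbour of Nanog. Polycomb genes had 10.7 ± 6.98 (15 genes, 2.08-fold, adjusted permutation p = 0.00107), with 27 at Cbx7. Housekeeping genes had 9.87 ± 5.75 (15 genes, 1.80-fold, adjusted permutation p = 0.0048), with 20 at Actb, and formative genes 8.77 ± 4.53 (13 genes, 1.88-fold, adjusted p = 0.0128), with 18 at Dnmt3a and 13 at Otx2. The spread between genes of a list was wide, and neighbours such as Nanog, Dppa3 and Gdf3 share distal peaks, so list members are not independent.

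Trophectoderm genes had 7.86 ± 4.13 distal peaks (14 genes, 1.67-fold, adjusted permutation p = 0.0494), with 16 at Tfap2c. Two-cell-like genes had 1.77 ± 1.3 (13 genes, 0.388-fold, adjusted permutation p = 0.0192), with 0 at Zscan4d. In peaks placed at random this list had a mean ratio of 0.736 (0.530 to 0.919 over 20 simulations), so part of its low ratio arises without any effect. Olfactory receptor genes had 0.771 ± 1.38 (1105 genes, 0.137-fold, adjusted permutation p = 0.00107), or 0.377-fold when lists were matched on gene length. R-loop genes had 5.82 and H2A.Z genes 7.14 distal peaks per gene, which did not pass (adjusted permutation p = 0.759 and 0.148). The other lists that did not pass lay between 3.17 for differentiated tissues and 6.56 for the Hox genes, with mesoderm at 6.07, neuroectoderm at 4.8, primitive endoderm at 5.40, germline at 3.87 and fibroblast at 6.53. The trophectoderm call was lost in 4 of 6 alternatives, within 100 kb (adjusted permutation p = 0.138), without matching (0.0988), with peaks wider than the median (0.055) and matched on gene length (0.092). The two-cell-like call was also lost in 4, within 20 kb (0.282), with wider peaks (0.0995), matched on length (0.075) and outside protein-coding genes (0.403). The housekeeping call was lost within 20 kb (0.0818) and with wider peaks (0.0624), and the formative call within 100 kb (0.0821). In peaks placed at random the olfactory receptor list was called in 20 of 20 simulations with a mean ratio of 0.827, so only a ratio well below that value is informative.

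**Figure D3:**
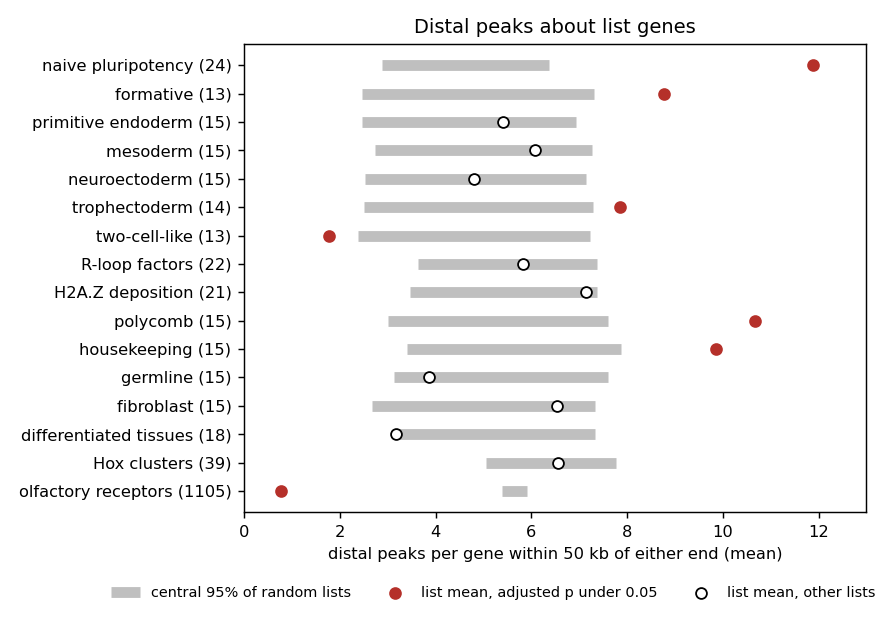
Mean number of distal peaks per gene within 50 kb of either gene end (x axis) for each list, with the number of genes in brackets. Grey bars give the central 95% of 10000 random lists matched on local gene density, and filled points mark an adjusted p under 0.05, the naive pluripotency list lying at 11.9.

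The stretch from Gdf3 and Dppa3 to Nanog on chromosome 6 shows this arrangement. Between 122576424 and 122764633 (188 kb) the list held 33 peaks, or 175 per Mb, against 28.9 per Mb over all chromosomes. Of these, 6 lay at ends of the 5 protein-coding genes there and 27 were distal. The peak at Nanog lay at 122707401 to 122707523, over the lower gene end. The peak nearest to Dppa3, which encodes the maternal factor Stella, lay inside the gene at 122627588 to 122627715. The gene table holds no exons, so whether these peaks were exonic or intronic was not determined here.

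**Figure D4:**
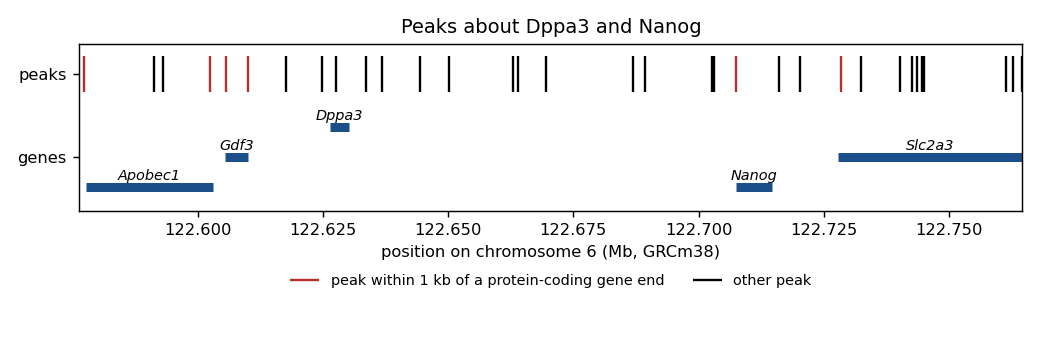
Peaks (upper ticks) and protein-coding genes (bars) between 122576424 and 122764633 on chromosome 6 (x axis, Mb, GRCm38). Red ticks are the 6 peaks within 1 kb of a protein-coding gene end and black ticks the other 27 peaks, 11 of which lie between Dppa3 and Nanog.

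Peak density followed gene density over the autosomes, and chromosome X lay far below. Chromosome 11 had the highest density, 48.6 peaks per Mb with 13.5 protein-coding genes per Mb, and chromosome 3 the lowest among autosomes, 23.3 peaks per Mb with 6.27 genes per Mb. Chromosome X had 1486 peaks, or 8.87 per Mb, with 5.75 genes per Mb. Genes on X had a peak at an end less often, 389 of 963 (40.4%), than autosomal genes, 13031 of 20558 (63.4%). The odds ratio was 0.391 (95% interval 0.342 to 0.448, Fisher's exact test p = 4.53e-45). The p-value and interval take genes as independent and do not measure the spread between chromosomes. X holds families such as the 33 Rhox genes, of which 2 had a peak at an end. Among autosomes the share ran from 53.1% on chromosome 7 to 71.5% on chromosome 12, so X lay below each of them. Of the 22 genes on X of ubiquitously expressed families 17 had a peak at an end, Rpl10, Rps4x and Eif2s3x among them, against 93.4% of autosomal genes of these families. Chromosome Y held 20 peaks.

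**Figure D5:**
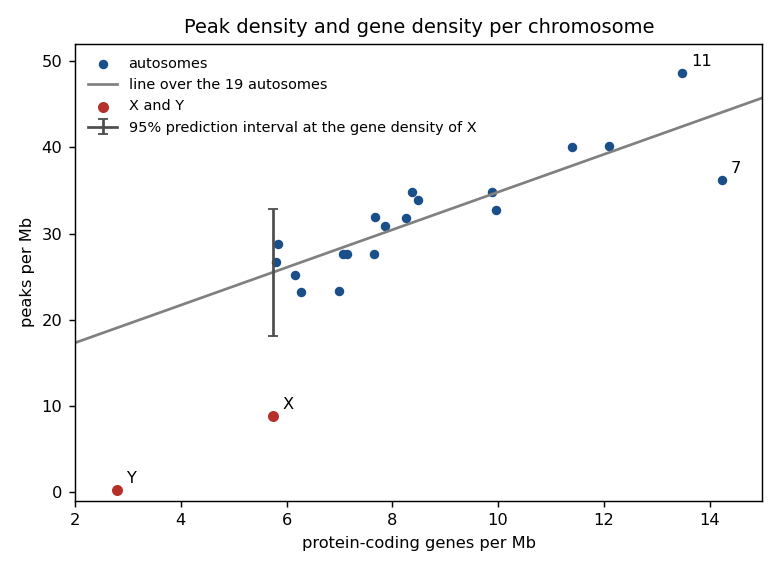
Peaks per Mb (y axis) against protein-coding genes per Mb (x axis) for each chromosome, with the least-squares line over the 19 autosomes. The bar is the 95% prediction interval of that line at the gene density of X, 18.1 to 32.9 peaks per Mb, and X lies at 8.87.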

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

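The comparison of the scaffold with chromosome windows was chosen after the peaks on it were seen. No sample or group could be set apart from the others, since the peaks carry no value per sample, and what follows lies outside the gene comparisons. On 7 unplaced or unlocalized scaffolds the list held 28 peaks. This was above a fixed floor of 3 used only to flag counts, which is not a test. Of these, 18 lay on 1 unplaced scaffold within 64.1 kb, or 281 peaks per Mb against 28.9 per Mb on the chromosomes. Of 76968 chromosome windows of that length, each starting at a peak, 0.218% held as many, the median window holding 5 peaks and the fullest 23.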

How the results depend on the processing

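These alternatives were added after the data were seen: the shift of all peaks of a chromosome, autosomes alone, peaks anywhere in the gene, genes with no other gene end within 2 kb, matching or permutation within deciles of gene length or, at gene ends, of gene density, and distal peaks outside every protein-coding gene. Of the alternatives to a test, 209 kept direction and side of the threshold, 17 newly passed, 19 no longer passed and 26 changed direction. Of the alternatives to a count of lists, 21 stayed within 1.5 times the main count and 11 moved, and all 8 alternatives to the share of genes lay outside the exact 95% interval of the main share. No paired analysis was possible because the peak list carries no value of any sample, and for the same reason no sample could be left out. Not run for want of strand, sequence or scores were the alternatives on the 5 prime end, repeat masking, GC or CpG matching, motifs, GC skew, N-free length and every Dox test. Where no cause is given below, the cause was not tested.

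The share of peaks at gene ends stayed above random placement in all 7 alternatives (2.84-fold to 9.39-fold), as did the direction of each class in both of its alternatives, 1 of which took the commonest class over 5 positions of a peak. The share of genes with a peak at an end was 56.4% with 500 bp, 73.8% with 5 kb, 38.6% over all annotated genes, 60.9% by peak centre, 41.5% with peaks wider than the median, 73.1% anywhere in the gene, 52.3% for genes with no other end nearby and 63.4% on autosomes.

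For lists at gene ends, values are percentage points, list minus other genes. The R-loop and olfactory receptor lists held in all 10 alternatives, and differentiated tissues and polycomb in 9 each. With 500 bp, naive pluripotency (27.0) and trophectoderm (-35.0) newly passed, H2A.Z no longer did (19.9), and formative (5.19) and mesoderm (-9.70) changed direction without passing. With 5 kb, naive pluripotency (22.1), neuroectoderm (26.2) and fibroblast (-33.8) newly passed. There formative (26.2, passing), trophectoderm (11.95) and Hox (23.7, passing) changed direction, with 7 lists above in place of 3. Neighbouring Hox genes can share a peak in such windows. Over all annotated genes, where the other genes include many non-coding ones with few peaks, naive pluripotency (44.8), neuroectoderm (48.1), housekeeping (34.8) and germline (41.4) newly passed. There two-cell-like (-23.2) and differentiated tissues (-21.9) no longer did, formative (22.9), primitive endoderm (8.07), fibroblast (1.41) and Hox (15.3) changed direction without passing, and 7 lists lay above and 1 below. By peak centre formative changed direction (0.608). With peaks wider than the median formative did too (12.3), two-cell-like (-26.2), H2A.Z (15.6) and polycomb (18.5) no longer passed, and 1 list lay above. Anywhere in the gene, naive pluripotency (26.9) and neuroectoderm (26.9) newly passed, formative (26.9, passing), primitive endoderm (13.5), trophectoderm (12.6) and Hox (3.79) changed direction, and 6 lists lay above. For genes with no other end nearby, naive pluripotency (29.6) and neuroectoderm (38.6) newly passed, formative (11.4), housekeeping (-2.29) and Hox (13.1) changed direction without passing, and 5 lists lay above. Within deciles of gene length two-cell-like (-29.4) and H2A.Z (21.9) no longer passed. Within deciles of gene density naive pluripotency newly passed (26.1) and formative changed direction (3.09).

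For distal peaks, values are list mean minus random lists. Naive pluripotency, polycomb and olfactory receptors held in all 6 alternatives, though matching on length took the olfactory difference from -4.87 to -1.27. Within 20 kb two-cell-like (-0.884) and housekeeping (1.48) no longer passed and differentiated tissues newly did (-1.27). Within 100 kb formative (4.57) and trophectoderm (3.90) no longer passed, neuroectoderm (-0.0812) and Hox (-0.393) changed direction without passing, and 3 lists lay above in place of 5. Without matching trophectoderm no longer passed (2.61) and neuroectoderm changed direction (-0.437). With peaks wider than the median trophectoderm (1.85), two-cell-like (-1.16) and housekeeping (1.58) no longer passed, leaving 3 lists above and 1 below in place of 2. Matched on length, trophectoderm (2.47) and two-cell-like (-2.02) no longer passed, Hox newly did (1.88), primitive endoderm (-0.236), neuroectoderm (-0.0640) and R-loop factors (-0.118) changed direction, and 1 list lay below. With peaks outside every protein-coding gene two-cell-like (-0.744) no longer passed, Hox newly did (1.17), R-loop factors changed direction (-0.498), and 1 list lay below. Depth limits the absence of peaks, which is unknown here.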

Other observations

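The gene families, RNA classes, clusters of peaks, Firre and Hprt were looked at only after the peak list had been seen, and the tests on families matched on gene length or in randomly placed peaks, on ubiquitous genes without a peak at an end and on X genes without kinases and copies were chosen after the results they follow. Among 111 families of at least 20 protein-coding genes with a shared symbol stem, 41 had a peak at an end more often and 33 less often than other genes (Fisher's exact test, adjusted over families). All 28 Polr genes, which encode RNA polymerase subunits, and all 29 Mrps genes of the small mitochondrial ribosomal subunit had a peak at an end, as did 34 of 35 Vps genes of vesicle sorting. The vomeronasal receptor genes (Vmn) had 4 of 352, keratin-associated protein genes (Krtap) 1 of 56, and alpha-defensin (Defa) and prolactin (Prl) family genes 0 of 28 and 0 of 25. Within deciles of gene length 28 families lay above and 32 below. There the difference from other genes went from -61.5 to -34.7 percentage points for Vmn, from -60.0 to -13.7 for Krtap and from -61.7 to -13.2 for Defa, which no longer passed (permutation test, adjusted p = 0.0693), and stayed at -61.8 for Prl. The handling of reads that match several places is unknown, so missing peaks in families of similar copies are uncertain. The distal test of families matched on gene density called on average 6.45 families above and 10.2 below in peaks placed at random (20 sets), and matched on gene length 4.85 and 3.7, so counts of families by distal peaks are not given. The TNF receptor family (Tnfrsf, 20 genes), called in 0 of these sets, had 9.25 ± 4.58 distal peaks per gene (SD) against 5.07 in density-matched lists and 5.53 in length-matched ones (permutation test, adjusted p = 0.00462 and 0.00822). Of the 111 families it had the highest ratio to density-matched lists. These sets place peaks independently of each other, while the real distal peaks gather in clusters, so the 0 calls do not exclude chance. Among genes over 10 kb from any protein-coding gene, 108 of 206 tRNA genes had a peak at an end (52.4%, exact 95% interval 45.4 to 59.4%), against 6.16% in random placements. For lncRNA genes the share was 19.7% against 12.0%, and for pseudogenes 5.52% against 8.73%. The interval for tRNA genes takes them as independent, although 1 peak can count for several neighbouring genes.

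Peaks gathered in clusters. Linking distal peaks less than 12.5 kb apart gave 324 clusters of at least 10 peaks, against a mean of 0.77 and at most 5 in 200 random placements. The cluster with the most peaks lay over Plekha7 (31 peaks, chromosome 7, 116156652 to 116309758). Next came clusters of 27 peaks each over Tcf7l1 (chromosome 6, 72636161 to 72774762) and over Sbk1 (chromosome 7, 126217129 to 126359334). Tcf7l1 encodes a repressor of the pluripotency network. A cluster on X of 20 peaks lay over the lncRNA gene Firre (chromosome X, 50563120 to 50635321), where 17 peaks fell inside the gene, 1.14% of all peaks on X. The next lncRNA gene on X held 8, and of 12637 lncRNA genes only 3, Firre included, held at least as many as Firre. Of these, Gm31615 held more. Firre is 72.2 kb long, and these counts were not set against gene length. Hprt, which E14Tg2a cells are known to lack in functional form, lay in a peak-free stretch of 90.7 kb, and 24.1% of the gaps between peaks on X were at least as long. On chromosome Y, 16 of the 20 peaks lay between 90723719 and 90825550.

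Chromosome X held 8.87 peaks per Mb. Its low gene density does not account for this, because the line of peak density on gene density over 19 autosomes put X at 25.5 peaks per Mb with a 95% prediction interval of 18.1 to 32.9, and distal peaks alone lay at 6.18 against an interval of 14.6 to 27.0. Tissue-restricted genes on X may contribute: ubiquitous families had a peak at an end in 17 of 22 genes on X and 93.4% of autosomal genes (odds ratio 0.242, 95% interval 0.0797 to 0.883), which on its own would speak against gene content, but 3 of the 5 genes without were the kinase gene Rps6ka6 and the copies Ube2dnl1 and Ube2dnl2, and without kinases and copies the odds ratio was 0.452 with an interval of 0.0980 to 4.25. A lower read depth from a single X could also remove weak peaks, but the median width of peaks at gene ends was 4 bp larger on X than on autosomes (permutation p = 0.119), which decides neither way, so both explanations stay open and cannot be told apart from this list. No biological explanation beyond gene content was tested.

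Some ubiquitous genes lacked a peak at an end. Of 662 genes in ubiquitous lists and families 50 had none, Actb among them. The kinases and copies left out of the second comparison of X genes were kept here, so Rps6ka6, Ube2dnl1 and Ube2dnl2 are also among the 50. A candidate explanation is that the outer gene ends of the annotation lie away from the start site in use: 70.0% of the 50 (exact 95% interval 55.4 to 82.1%) had a peak inside the gene or within 5 kb, against 39.8% of other genes without a peak at an end (Fisher's exact test p = 2.95e-05). The other genes include 1084 olfactory receptor genes without a peak at an end. Of all 1105 olfactory receptor genes 6.61% had a peak within 5 kb of an end, which lowers the 39.8%. The higher peak density around ubiquitous genes was not separated from the candidate explanation, and no biological explanation was tested.

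Gene length was considered for the many distal peaks around naive pluripotency genes, since long genes hold more distal peaks. The genes of the list were not longer, with a median of 12.8 kb against 17.2 kb for all protein-coding genes. This argues against length as the whole cause. Against 10000 random lists matched on length the mean of 11.9 stayed above 5.13 (permutation p = 0.0002, the smallest these draws can give). Random lists without matching had 5.23, so matching on length changed little and this test adds little to the lengths themselves. Local gene density was matched in the comparison itself. That these genes are surrounded by open regulatory regions in naive cells remains a hypothesis, since base composition and mappability were not tested and no other cell state was compared.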
